A study of Mus musculus with 4 samples.

How the data were processed

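Translating ribosome affinity purification (TRAP) followed by RNA sequencing was applied to the prefrontal cortex of adult male Crh-IRES-Cre mice, a line in which Cre recombinase is made from the locus of Crh, the gene of corticotropin-releasing hormone. Per the labels' protocols, the tissue was homogenized, EGFP-tagged polysomes were captured with antibodies against EGFP on magnetic beads, and the bound RNA was purified. The libraries analysed here were 1 Input and 3 immunopurified (IP) libraries, each made from 5 males, and no animal was treated. The labels did not say whether the animals of the Input were those of an IP, nor whether the IP libraries came from separate animals, so p-values measure only the spread between these libraries, which may in part be technical.

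The authors deposited raw read counts per gene, per the file headers with an Entrez identifier and a symbol for each gene and 1 library per file. The submitters' processing notes named STAR 2.0.0e, HTSeq (without a version) and the mouse genome build mm10. The names of the deposited count tables also held the word subread, which is another counting program, so the counter was not settled. The annotation, the treatment of multiply mapped reads and the strand of counting were not given in the sources used here. Whether reads of genes that overlap, or that have an antisense partner, were told apart in these counts is therefore unknown. Reads shared by near-identical copies may have been dropped or split.

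The tables held 24100 genes, of which 9 had no symbol and took at most 0.0221% of a library's counts. Total counts were 14474529 in the Input and 23548375, 10031072 and 12150980 in IP 1, 2 and 3. A single count was worth 0.0600 CPM (counts scaled by library size and TMM factor) in the Input and 0.0436, 0.107 and 0.0862 CPM in the IP libraries. A level of 0 counts allowed up to 3 counts, which is 0.180 CPM in the Input and 0.131, 0.321 and 0.259 CPM in the IP libraries, and such limits cover counting error only. No library was a copy of another, since a chi-square over genes per degree of freedom was at least 88.7 for each pair. No mitochondrially encoded gene was in the tables, so that list had no values.

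The counts were analysed in R 4.3.3. Genes were kept by filterByExpr of edgeR 4.0.16 with its minimum count of 10, which left 14636 genes, and libraries were scaled by TMM, with factors of 1.15 for the Input and 0.974, 0.932 and 0.955 for the IP libraries. IP was compared with Input by the quasi-likelihood F test of edgeR, two-sided, with Benjamini-Hochberg adjustment over the genes kept and a threshold of 0.05. Standard errors (SE) of log2 folds were the fold divided by the square root of F. With a lone Input, the spread came from the 3 IP libraries (2 residual degrees of freedom, with a prior of 17.0), and the Input was assumed to vary like them. The biological coefficient of variation was 0.787. All adjusted p-values of genes are from this test unless DESeq2 or limma is named.

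Before the data were examined, 36 gene lists, the test and most alternatives were fixed. Of these lists, 35 had at least 3 tested members and were compared with all other genes by camera (limma 3.58.1, preset correlation between genes of 0.01, Benjamini-Hochberg over the 35 lists). Lists were also tested with a correlation estimated from the residuals, and with fry, which asks whether the genes of a list move on balance in a single direction and makes no comparison with other genes. Both rest on 2 residual degrees of freedom, so a call lost with them need not come from correlation between genes. Over all lists, 34 genes belonged to more than 1 list, so lists were not independent. Percentiles of list medians were taken among 10000 random lists matched on mean expression. Medians for single libraries used log2 ratios to the Input with 0.5 CPM added.

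Genes to be named were also fixed beforehand. They were Crh, and up to 10 genes per direction with the largest log2 fold among those past the threshold. These had to reach 5 CPM in the higher group, with all 3 IP libraries on the same side of the Input, and gene models known only by a number were counted but not named. Further named were up to 4 members past the threshold and up to 2 of the most abundant other members of each list, and a set of first-named markers in any case (Vip, Sst, Pvalb, Lamp5, Gad1, Gad2, Slc32a1, Slc17a7, Cck, Calb2, Npy, Crhr1, Crhbp). A few genes that this rule takes are not reported here. Outside this rule, and chosen after their values were seen, were Erbb4, Prox1, Cnr1, Penk and Scg2, which complete the called members of their lists, and Lhx6, P2ry12, Snhg11 and Gm20594. The same holds for every gene that only the closing section names.

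Alternatives were DESeq2 1.42.0, limma-voom, other scalings (RLE, upper quartile, library totals), no low-count filter, a mean of at least 5 CPM, a robust prior, an adjusted p under 0.01, and leaving out each IP library. Removal of a trend of fold with coding length was added after the data were seen. Gene positions, coding lengths and exon overlaps came from GENCODE and RefSeq annotation of GRCm38, the assembly that mm10 names, matched on the Entrez identifier. Of the tested genes, 13757 (93.99%) had a coding length.

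The gene test was tested on counts simulated for these 14636 genes from the real means, dispersions and library sizes, with 200 genes changed. For a true log2 fold of 2 it called 11 of 50 genes with the right sign, and for -2 it called 5 of 50. For a true log2 fold of 4 it called 48 of 50, and for -4 it called 17 of 50, so falls were harder to detect than rises. Of its 88 calls, 7 were unchanged genes. On the same simulated counts DESeq2 made 247 calls, of which 136 were unchanged genes, and limma-voom made 77, of which 4 were unchanged. The list test called the 1 changed list, of 15 genes raised by 4 on the log2 scale, and 0 of 35 unchanged lists. Genes were simulated independently of each other, so this does not test lists of correlated genes or smaller shifts. The simulated Input varied like the IP libraries, an assumption that a lone Input cannot check, so these rates hold only under it. All 200 changed genes had a mean of at least 5 CPM, so the rates do not cover less abundant genes.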

Results

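RNA bound to tagged ribosomes was compared with the RNA of whole prefrontal cortex in adult male Crh-IRES-Cre mice, a line used to reach neurons that express Crh, the stress peptide corticotropin-releasing hormone. The series is described as a profile of cortical interneurons. The libraries used were 1 Input and 3 IP libraries of 5 males each, with 14474529 counts in the Input and 10031072 to 23548375 in the IP libraries. Counts were found for 17141 genes in the Input and for 14691, 13956 and 14172 genes in IP 1, 2 and 3. The comparison of IP with Input asked which transcripts were enriched on, or depleted from, the captured ribosomes. Values below are TMM-scaled CPM, with the SD over the 3 IP libraries, and the Input had no replicate.

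Crh itself (Entrez 12918, chromosome 3, 19693401 to 19695396 in GRCm38, protein coding), the gene whose locus drives Cre in this line, was at 1.32 CPM in the Input (22 counts) and at 501, 174 and 193 CPM in IP 1, 2 and 3. Its mean in IP was 289 ± 184 CPM (SD, n = 3), a log2 fold of 7.77 ± 0.87 (SE, adjusted p = 9.66e-05), higher in all 3 IP libraries. In all, 67 of 14636 genes (0.458%) differed between IP and Input, of which 60 were higher and 7 lower in IP, and each of the 67 differed at least 2-fold with all 3 IP libraries on the same side of the Input. Among the rises were 4 genes of the Vip class and 6 markers of interneurons from the caudal ganglionic eminence (CGE), and 37 of the 60 higher genes were on none of the fixed lists. The excitatory neuron genes Nrn1 and Nrgn and the nuclear RNA Malat1 were among the falls. Without IP 1 the log2 fold of Crh was 7.09. The call of Crh ended with limma-voom (log2 fold 7.73, adjusted p = 0.426), and over the 12 alternatives its adjusted p ran from 4.91e-26 to 0.426. The count of 67 was 182 with DESeq2, 108 without a low-count filter, 210 without IP 1 and 105 without IP 2, and the split of higher against lower was 50 to 15 with library totals alone and 51 to 15 with upper-quartile factors.

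**Figure D1:**
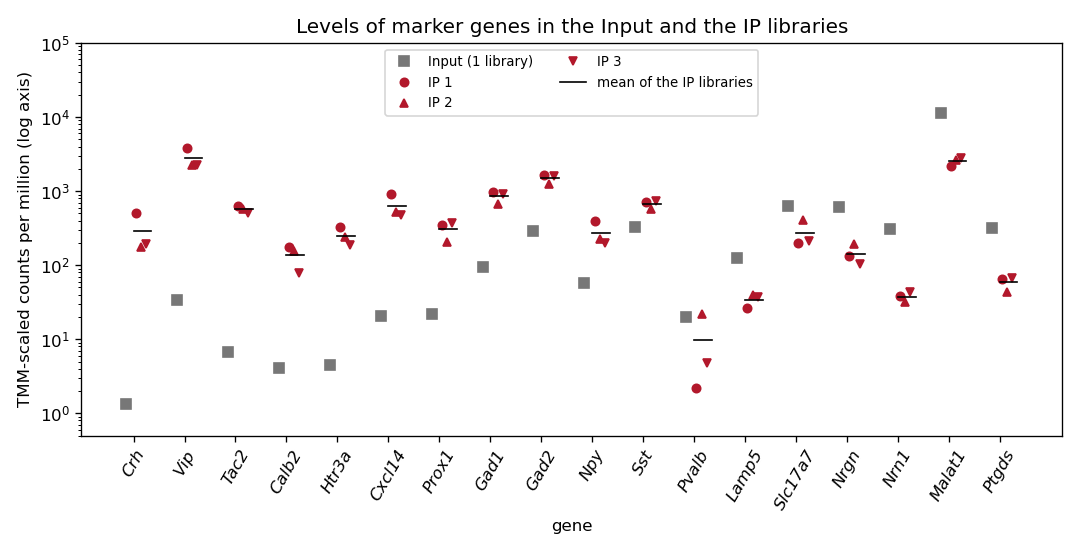
TMM-scaled CPM (log axis) of 18 marker genes in the Input (grey squares) and in the 3 IP libraries (red symbols), with a black line at the mean of the IP libraries. Crh lay at 1.32 CPM in the Input and between 174 and 501 CPM in the IP libraries, while Malat1 and Nrn1 lay lower in each IP library than in the Input.

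Of 14 markers shared by GABAergic neurons 5 rose, and 10 passed when adjusted over the list alone. The list was higher by camera (median log2 fold 2.31, adjusted p = 7.42e-27; adjusted p = 0.197 with an estimated correlation). Gad1, which makes the GABA-synthesizing enzyme GAD67, rose from 94.3 CPM to 856 ± 167 CPM (SD, n = 3), a log2 fold of 3.18 ± 0.45 (SE, adjusted p = 0.000692). Gad2, the gene of GAD65, rose from 289 to 1506 ± 222 CPM, a log2 fold of 2.38 ± 0.39 (adjusted p = 0.00279). The homeobox gene Dlx1 (log2 fold 4.22 ± 0.59), the noncoding RNA Dlx6os1 (3.50 ± 0.57) and the neuregulin receptor gene Erbb4 (2.25 ± 0.42) also rose. Slc32a1, the vesicular GABA transporter, was at 22.3 CPM in the Input and 148 ± 38.3 CPM in IP (log2 fold 2.73 ± 0.62, adjusted p = 0.0651), and 24.92% of its exon bases are shared with another gene.

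Of 10 markers of interneurons born in the CGE 6 rose, and 9 passed when adjusted over the list alone. The list was higher by camera (median log2 fold 4.02, adjusted p = 3.81e-37; adjusted p = 0.195 with an estimated correlation). The members that rose included Htr3a, the ion channel subunit gated by serotonin, which went from 4.56 to 251 ± 68.8 CPM (log2 fold 5.78 ± 0.67, adjusted p = 0.000107), the chemokine gene Cxcl14 (4.93 ± 0.56), and the transcription factor gene Nr2f2 (4.57 ± 0.82). Nr2f2 was at 435, 126 and 125 CPM in IP 1, 2 and 3, and its log2 fold was 3.68 without IP 1 (adjusted p = 0.000345). The RNA-binding protein gene Adarb2 (4.22 ± 0.52), the homeobox gene Prox1 (3.81 ± 0.57) and the cannabinoid receptor gene Cnr1 (2.45 ± 0.41) made up the rest of the 6.

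Vip, the gene of vasoactive intestinal peptide (Entrez 22353, chromosome 10, 5639193 to 5647617), went from 33.8 CPM in the Input to 3802, 2253 and 2254 CPM in the IP libraries, a log2 fold of 6.36 ± 0.51 (SE, adjusted p = 1.95e-06). In the Vip class 4 of 10 members rose, and 8 passed when adjusted over the list alone. The list was higher by camera (median log2 fold 4.35, adjusted p = 8.76e-32; adjusted p = 0.195 with an estimated correlation). Besides Vip the members that rose were Tac2, the gene of neurokinin B (6.66 to 573 ± 59.8 CPM, log2 fold 6.43 ± 0.56), Calb2, which encodes the calcium-binding protein calretinin (5.05 ± 0.80), and the growth factor gene Igf1 (4.56 ± 0.53). With limma-voom the calls of Htr3a (adjusted p = 0.0876), Nr2f2 (0.364) and Calb2 (0.312) ended, and those of Vip and Tac2 held under all 12 alternatives.

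Sst, the gene of somatostatin, was at 332 CPM in the Input and 678 ± 86.5 CPM in IP (log2 fold 1.03 ± 0.38, adjusted p = 0.714), above the Input in all 3 IP libraries but not past the threshold. Pvalb, the gene of parvalbumin, was at 20.3 CPM in the Input and at 2.22, 21.9 and 4.83 CPM in IP 1, 2 and 3 (log2 fold -1.07 ± 1.26). The lists of the Sst class (median log2 fold 0.44, adjusted p = 0.404) and the Pvalb class (0.12, adjusted p = 0.404) did not pass. In IP 1, 2 and 3 the medians were -0.61, 0.50 and 1.01 for the Sst class and -0.78, 0.11 and 0.38 for the Pvalb class. The fitted median of the Pvalb class turned to -0.16 with library totals and -0.097 with upper-quartile factors. Among 7 regulators of interneurons from the medial ganglionic eminence, the synaptic adhesion gene Elfn1 alone rose (log2 fold 2.66 ± 0.51, adjusted p = 0.0141, ended by limma-voom at 0.0757). Lhx6 was at 39.9 CPM in the Input and 40.2 ± 28.1 CPM in IP, and Satb1 at 240 and 212 ± 58.0 CPM. That list did not pass (adjusted p = 0.193), and its median of 0.011 turned to -0.26 with library totals and -0.20 with upper-quartile factors.

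In the Lamp5 class 2 of 10 members rose, the receptor tyrosine kinase gene Kit (log2 fold 3.90 ± 0.54) and Rgs12, a regulator of G-protein signalling (4.11 ± 0.58). When adjusted over the list alone, 4 members were higher and 1 lower. The class marker Lamp5 itself was at 126 CPM in the Input and 34.2 ± 7.06 CPM in IP (log2 fold -1.88 ± 0.62, adjusted p = 0.480), and Npy, the gene of neuropeptide Y, at 58.3 and 274 ± 107 CPM (2.23 ± 0.54, adjusted p = 0.0936). The list was higher by camera (median log2 fold 0.85, adjusted p = 5.09e-05; adjusted p = 0.197 with an estimated correlation).

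Of 20 neuropeptide genes 6 rose, and 10 passed when adjusted over the list alone. Besides Crh, Vip, Tac2 and Igf1 these were Penk, the gene of the enkephalins (24.4 to 481 ± 108 CPM, log2 fold 4.30 ± 0.53), and Scg2, the gene of secretogranin II (2.12 ± 0.45, adjusted p = 0.0338). Of the exon bases of Penk 14.26% are shared with another gene. The call of Scg2 ended without IP 3 (adjusted p = 0.0544), with library totals (0.0870), with upper-quartile factors (0.0774), with a mean of at least 5 CPM (0.0624) and with limma-voom (0.0540). Cck, the gene of cholecystokinin, was at 435 CPM in the Input and 508 ± 75.8 CPM in IP (log2 fold 0.23 ± 0.38). The list was higher by camera (median log2 fold 1.61, adjusted p = 2.25e-21; adjusted p = 0.195 with an estimated correlation), and 4 of its 6 calls were also made by limma-voom.

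Among 27 receptors for monoamines and acetylcholine 2 rose, Htr3a and the alpha-1 adrenergic receptor gene Adra1b (22.1 to 222 ± 20.2 CPM, log2 fold 3.33 ± 0.56), and 2 passed when adjusted over the list alone. That list was higher by camera (median log2 fold 0.81, adjusted p = 0.000457; adjusted p = 0.197 with an estimated correlation). Among 26 receptors for neuropeptides and opioids Grpr, the receptor for gastrin-releasing peptide, rose (1.62 to 88.3 ± 27.1 CPM, log2 fold 5.76 ± 0.94, adjusted p = 0.00301). The median of that list was -0.49, its mean 0.011 and its camera direction up, so they differed in sign, and the list did not pass (adjusted p = 0.898). Limma-voom ended the calls of Adra1b (adjusted p = 0.0591) and Grpr (0.425). None of 10 genes of CRH and glucocorticoid signalling was called, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. Crhr1, a receptor for CRH, was at 8.52 CPM in the Input and 3.12 ± 2.12 CPM in IP, Crhbp, the CRH-binding protein, at 11.1 and 15.3 ± 8.45 CPM, and Nr3c1, the glucocorticoid receptor, at 173 and 124 ± 20.7 CPM.

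Other genes with the largest rises belonged to none of the lists. Pou2af1, a transcriptional coactivator known from B cells, had 1 count in the Input and 1856 counts over the IP libraries, a pooled ratio of 705 (95% counting interval 126 to 27870), and was at 32.3, 52.3 and 54.0 CPM in IP 1, 2 and 3 (adjusted p = 0.00261). Ctse, the gene of the protease cathepsin E, went from 1.02 to 123 ± 41.1 CPM (log2 fold 6.90 ± 0.92, adjusted p = 0.000369). Irf4, a transcription factor of the interferon regulatory family, went from 0.720 to 45.4 ± 5.58 CPM (log2 fold 5.96 ± 1.19, adjusted p = 0.0203). The autophagy gene Atg7 rose from 25.4 to 1369 ± 577 CPM (log2 fold 5.75 ± 0.57) and Yeats2, which encodes a reader of histone acylation, from 31.9 to 1712 ± 678 CPM (5.75 ± 0.55). In IP 1, 2 and 3 Atg7 was at 1018, 1055 and 2036 CPM and Yeats2 at 1101, 1595 and 2442 CPM. Both were thus highest in IP 3, whereas Crh and Vip were highest in IP 1. Limma-voom ended the calls of Pou2af1 (adjusted p = 0.563), Ctse (0.441) and Irf4 (0.566).

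Of 16 genes of excitatory neurons 2 fell, 5 passed when adjusted over the list alone, and 11 lay below the Input in all 3 IP libraries. The list was lower by camera (median log2 fold -1.19, adjusted p = 4.31e-11; adjusted p = 0.197 with an estimated correlation), while a second list of excitatory genes, the layer markers, did not pass (adjusted p = 0.0663). Nrn1, the gene of the growth-promoting protein neuritin, fell from 311 CPM to 37.7 ± 5.76 CPM (log2 fold -3.04 ± 0.48, adjusted p = 0.00225), and 22.28% of its exon bases are shared with another gene. Nrgn, the gene of the postsynaptic protein neurogranin, fell from 616 to 143 ± 46.3 CPM (log2 fold -2.11 ± 0.40, adjusted p = 0.0141). Slc17a7, the vesicular glutamate transporter VGLUT1, was at 633 CPM in the Input and 272 ± 113 CPM in IP (log2 fold -1.22 ± 0.41, adjusted p = 0.535), and Camk2a at 2902 and 3909 ± 1213 CPM (0.43 ± 0.34).

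Outside that list, Malat1, a long noncoding RNA kept in the nucleus, fell from 11174 to 2558 ± 329 CPM (log2 fold -2.13 ± 0.25, adjusted p = 0.000131). Ptgds, the gene of prostaglandin D synthase, fell from 316 to 58.5 ± 13.5 CPM (log2 fold -2.43 ± 0.46) and Fam107a from 428 to 110 ± 16.0 CPM (-1.96 ± 0.41). Cdr1 fell from 7296 to 1563 ± 330 CPM (log2 fold -2.22 ± 0.28), but all of its exon bases lie within an antisense gene. Whether reads of the pair were told apart in the counts is unknown, so the fall may belong to either. Chosen after its values were seen, the gene model Gm20594 completed the 7 falls (223 to 5.98 ± 2.78 CPM, log2 fold -5.22 ± 0.65). Of 12 nuclear-retained noncoding RNAs 1 fell, Malat1, and when adjusted over the list alone 4 were lower and 2 higher. Meg3 had a log2 fold of -1.23 ± 0.32 (adjusted p = 0.160) and Snhg11 of -1.35 ± 0.33 (adjusted p = 0.0963). The list was lower by camera (median log2 fold -0.21, adjusted p = 0.0174; adjusted p = 0.327 with an estimated correlation), although its mean log2 fold was 0.15 and its median lay at the 5.59th percentile of random lists matched on abundance. This call ended without IP 1 (adjusted p = 0.0920), without IP 3 (0.0899) and without a low-count filter (0.405).

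The lists of astrocyte, oligodendrocyte and microglial markers were lower in IP by camera but not with an estimated correlation, with no single member called by edgeR, DESeq2 or limma-voom. The list of oligodendrocyte precursors did not pass (median -1.31, adjusted p = 0.193), although its median lay at the 0.01th percentile of random lists matched on abundance. Of its 10 members 6 lay below the Input in all 3 IP libraries and 2 above. Of 16 astrocyte markers 13 lay below the Input in all 3 IP libraries (median log2 fold -0.998, adjusted p = 0.000251; adjusted p = 0.406 with an estimated correlation), with 1 lower at an unadjusted p under 0.05. The glutamate transporter gene Slc1a2 was at 2122 CPM in the Input and 1794 ± 580 CPM in IP, and Aldoc at 303 and 180 ± 30.2 CPM. Of 16 oligodendrocyte markers 10 lay below in all 3 (median -1.12, adjusted p = 4.48e-05; adjusted p = 0.320 with an estimated correlation), with 3 lower at an unadjusted p. The myelin gene Mbp was at 215 CPM in the Input and 188 ± 74.0 CPM in IP. Of 15 microglial markers 13 lay below in all 3 (median -2.29, adjusted p = 3.29e-07; adjusted p = 0.197 with an estimated correlation), with 2 lower at an unadjusted p. P2ry12, a purine receptor of microglia, was at 21.2 CPM in the Input and 1.92 ± 0.48 CPM in IP. Adjusted over the list alone, 0 members of these 3 lists passed.

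Endothelial markers were higher in IP as a list (median log2 fold 2.77, adjusted p = 2.15e-06; adjusted p = 0.197 with an estimated correlation), with 10 of 14 above the Input in all 3 IP libraries. By edgeR 0 of the 14 were called, with 4 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom, and 2 passed when adjusted over the list alone. Slc2a1, the glucose transporter GLUT1, was at 22.8 CPM in the Input and at 49.9, 307 and 103 CPM in IP 1, 2 and 3, and Flt1, a receptor for vascular growth factors, at 3.06 CPM and at 44.7, 94.8 and 16.0 CPM. Meningeal fibroblast markers were lower by camera (13 tested, median -1.07, adjusted p = 0.00478; adjusted p = 0.271 with an estimated correlation), a call that ended with a mean of at least 5 CPM (0.125). Blood markers were also lower (7 tested, median -1.66, adjusted p = 0.00478; adjusted p = 0.271 with an estimated correlation). In each of these 2 lists 0 members were called by edgeR, DESeq2 or limma-voom and 1 was lower at an unadjusted p under 0.05.

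The lists of ribosomal and respiratory genes were higher in IP by camera but not with an estimated correlation, with 0 members called by any of the 3 tools and 0 at an unadjusted p under 0.05. For 41 ribosomal protein genes the median log2 fold was 0.39 (adjusted p = 0.0133; adjusted p = 0.463 with an estimated correlation), and the call ended without IP 1 (0.0710) and with a mean of at least 5 CPM (0.231). For 32 nuclear genes of oxidative phosphorylation it was 0.47 (adjusted p = 0.000999; adjusted p = 0.432 with an estimated correlation), and the call ended with a mean of at least 5 CPM (0.0507). Both medians stayed above 0 with library totals, at 0.12 and 0.20. Among random lists matched on abundance they lay at the 96.17th and 96.45th percentile, within the central 95%. The immediate early genes were lower as a list of 16 (median -0.29, adjusted p = 0.0229; adjusted p = 0.320 with an estimated correlation), a call that ended without IP 3 (0.0925) and without a low-count filter (0.327). By edgeR 0 of them were called, against 1 by DESeq2, 2 by limma-voom and 2 lower at an unadjusted p, and 2 were lower when adjusted over the list alone. The activity-regulated transcription factor gene Egr1 was at 1047 CPM in the Input and 405 ± 5.09 CPM in IP (log2 fold -1.37 ± 0.33, adjusted p = 0.0963), and Egr3 at 627 and 194 ± 39.1 CPM (-1.69 ± 0.38, adjusted p = 0.0549).

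**Figure D2:**
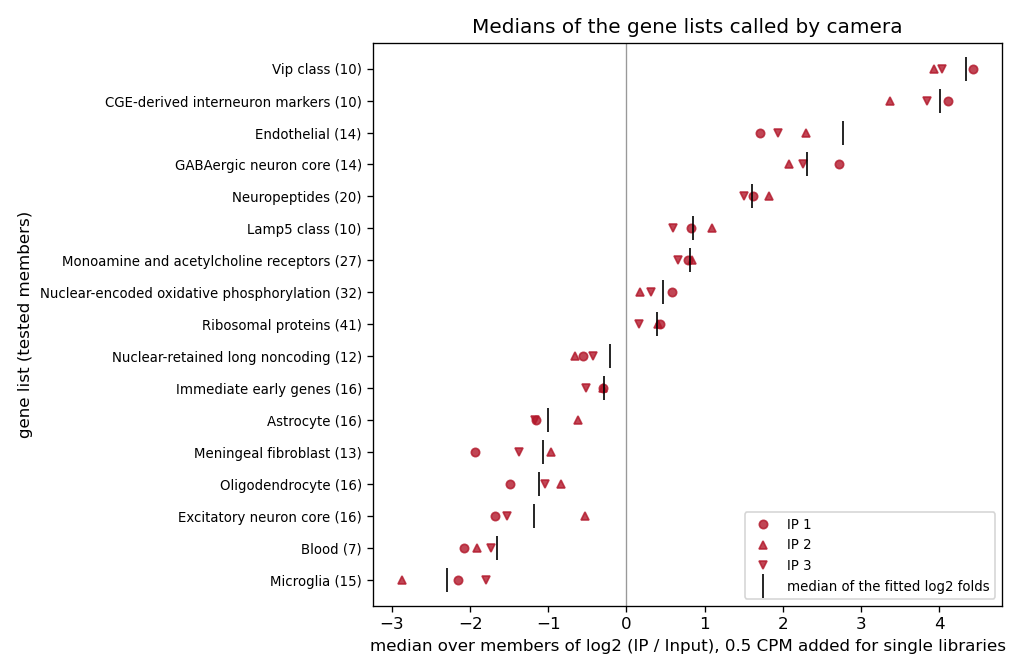
Median over members of the log2 ratio of IP to Input for the 17 gene lists past the threshold by camera, with tested members in parentheses. Red symbols are the 3 IP libraries and black ticks the medians of the fitted log2 folds, from -2.29 for microglia to 4.35 for the Vip class.

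In all, 9 lists were higher and 8 lower by camera, and 18 did not pass. With an estimated correlation 0 of the 17 calls held (8 lists at an unadjusted p under 0.05), and fry called 0 lists (10 at an unadjusted p under 0.05, lowest adjusted p = 0.0956). Both tests rest on 2 residual degrees of freedom, and the lowest adjusted p with an estimated correlation was 0.195. For endothelial (-0.00041), microglial (-0.051), meningeal fibroblast (-0.047) and blood markers (-0.053) the estimated correlation lay below the preset of 0.01. The same held for the Lamp5 class (-0.048), monoamine and acetylcholine receptors (-0.0046) and immediate early genes (-0.057). Correlation therefore does not explain the loss of those calls. Besides those given above, the lists that did not pass were excitatory layers (median -0.46, adjusted p = 0.0663) and pericytes and smooth muscle (1.19, adjusted p = 0.0975). Among random lists matched on abundance their medians lay at the 0th and the 99.84th percentile. The synaptic vesicle list (0.39, adjusted p = 0.0650), the heat shock list (0.31, adjusted p = 0.0897), the list of transcripts localised to axons and dendrites (0.43, adjusted p = 0.140) and the steroid and thyroid receptors (-0.35, adjusted p = 0.300) did not pass either. Nor did CRH and glucocorticoid signalling (0.50, adjusted p = 0.581) or the Y-linked genes with Xist (0.29, adjusted p = 0.635). In IP 1, 2 and 3 the medians were -8.6e-05, -0.029 and 0.19 for the former and 0, -0.56 and 0.33 for the latter. Some of these lists passed under other settings. Excitatory layers were lower with library totals (adjusted p = 0.0205), upper-quartile factors (0.0254), a mean of at least 5 CPM (0.00363) and without IP 2 (0.0280). Pericytes and smooth muscle were higher with library totals (0.0400), upper-quartile factors (0.04995), a mean of at least 5 CPM (0.00923) and without IP 1 (0.0264). Without IP 1 the axon and dendrite list (0.00354) and the ionotropic glutamate receptors (0.0263) were higher, and without a low-count filter the synaptic vesicle list (0.00374), the heat shock list (0.0297) and the glutamate receptors (0.0297). Medians turned below 0 with library totals for GABA receptors (0.024, adjusted p = 0.631), ionotropic glutamate receptors (0.25, adjusted p = 0.112), potassium channels (0.027, adjusted p = 0.635) and striatal projection neurons (0.16, adjusted p = 0.531), of which the glutamate receptors alone stayed above 0 with upper-quartile factors. The striatal list and the ependymal and choroid plexus list (1.052, adjusted p = 0.383) had medians above 0 and a camera direction down. For the 5 tested ependymal and choroid plexus genes the medians were -1.29, -2.12 and 0.34 in IP 1, 2 and 3. The fitted median of that list therefore does not show a rise shared by the IP libraries. Over the 237 different genes of the 18 lists edgeR called 2, Elfn1 and Grpr, both higher, with 22 higher and 7 lower at an unadjusted p under 0.05. DESeq2 called 4 of the 237 higher and 1 lower, and limma-voom called 0.

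An unadjusted p under 0.05 was found for 649 of the 14636 genes (469 higher and 180 lower in IP). This is fewer than the 732 expected if no gene differed and p-values were spread evenly. Since 67 genes passed after adjustment, the shortfall cannot be read as an absence of differences. The lone Input was assumed to vary like the IP libraries, so p-values need not be spread evenly, and the cause of the shortfall was not tested.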

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

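Removal of the coding-length trend was the alternative chosen after the data were seen. All 67 called genes kept their direction under every alternative run. Of them 66 were called again with RLE factors, 57 with library totals, 58 with upper-quartile factors, 59 with a mean of at least 5 CPM, 65 with a robust prior, 40 with limma-voom, 59 with the length trend removed, and all 67 with DESeq2 and without a filter. The median log2 fold of all genes moved by -0.27 with library totals, -0.22 with upper-quartile factors, -0.12 with limma-voom and -0.11 with a mean of at least 5 CPM, so folds near 0 have no settled sign. Depth limited genes near 1 count in the Input, as for Pou2af1. Leaving out mitochondrially encoded genes was not run, since none were in the tables. No paired analysis was possible because a single Input library was analysed here, and the file headers give each library a number of its own, so that Input and IP share none.

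Some counts moved by over 1.5 times, and the cause was not tested unless named. DESeq2 called 182 genes, 169 higher and 13 lower, and each was at least 2-fold (169 and 13). Without a low-count filter, where more genes were tested, 108 were called, 94 higher and 14 lower, again each at least 2-fold (94 and 14). With library totals 15 were lower, all at least 2-fold, and with upper-quartile factors also 15. With limma-voom 37 were higher and 14 lower, all at least 2-fold. At an adjusted p under 0.01, a stricter threshold by construction, 39 remained, 35 higher and 4 lower, all at least 2-fold. Leaving out each IP library gave 90 to 210 genes, 82 to 185 higher and 8 to 25 lower, and at least 2-fold 82 to 177 higher and 8 to 23 lower. The log2 fold of Crh was 7.73 with limma-voom, past no threshold (adjusted p = 0.426), and 7.09 to 8.03 without an IP library. Lists higher and lower in IP numbered 0 and 0 with an estimated correlation, and 0 and 0 by fry, both resting on 2 residual degrees of freedom. Under the other settings in which lists were tested, the counts of lists changed by less than 1.5 times. Lists were not tested with DESeq2, limma-voom, a robust prior or the length trend removed.

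Among the genes named in the report, those not called that changed sign were Lhx6 (-0.26 with library totals, -0.20 with upper-quartile factors, -0.10 with a mean of at least 5 CPM, -0.31 with limma-voom, -0.73 to 0.30 without an IP library), Cck (-0.045 with library totals), Crhbp (-0.0027 with limma-voom) and Mbp (-0.54 to 0.025 without an IP library).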

Other observations

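Tests of the endothelial pattern and the count for long genes alone were chosen only after the result was seen. Genes named here and not in the report, which are Lars2, the long genes and the 5 called genes of this paragraph, are on none of the lists and were chosen after their values were seen. Synpr, the gene of the synaptic vesicle protein synaptoporin, rose from 39.8 to 488 ± 215 CPM (SD, n = 3, log2 fold 3.62 ± 0.56). Kcnip1, which encodes a partner of potassium channels, rose from 36.8 to 304 ± 114 CPM (log2 fold 3.05 ± 0.56, ended by limma-voom at an adjusted p of 0.0775). Rgs16 and Rgs8, regulators of G-protein signalling like Rgs12, rose with log2 folds of 3.89 ± 0.80 and 2.30 ± 0.43, and limma-voom ended the call of Rgs16 (adjusted p = 0.364). Ap1s2, a subunit of the adaptor complex of clathrin-coated vesicles, rose from 40.5 to 743 ± 340 CPM (log2 fold 4.20 ± 0.56).

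The share of counts taken by Lars2 was 0.512% in the Input and 2.06%, 1.14% and 0.668% in IP 1, 2 and 3. RefSeq lists Gm20594 with a synonym of mitochondrial ribosomal RNA type, and it was at 223 CPM in the Input and at 6.19, 8.66 and 3.10 CPM in the IP libraries.

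With each of the 4 libraries in turn as the lone library, the real choice called 67 genes and the highest of the other choices 9. With 4 choices the share cannot go under 0.05.

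Called genes outside the lists included very long ones, such as Dync1h1 and Dst. Of these 37 genes 13 (35.1%) had over 4500 nt of coding sequence, against 16.2% in random lists matched on abundance (99.92nd percentile, a length set after the values were seen), while their median of 2223 nt lay at the 81.89th percentile. After removal of the trend of fold with coding length, 29 of 37 were still called. Among them were all 24 genes of up to 4500 nt, where the trend was small (log2 fold -0.13 at 1000 nt against 0.70 at 10000 nt). The count of 29 therefore says little about the trend as a cause of the calls of long genes. Of the genes over 4500 nt, though, 5 were still called: the calls of Dst, Ank2, Ank3, Sptan1, Hivep2, Sptbn1, Thsd7a and Tiam1 ended, since their log2 folds of 1.81 to 2.64 (SE 0.35 to 0.52) went to 0.79 to 2.22 (SE 0.34 to 0.51), but Thsd7a and Tiam1 moved by less than their SE, so a length trend may account for the call in the other 6, of which Dst and Ank3, like Tiam1, also lost it with library totals, upper-quartile factors and limma-voom (Thsd7a with limma-voom). Across genes, which are not independent replicates, fold followed 3' UTR length given coding length (partial rank correlation 0.0135) and GC content (0.0101) less than coding length (0.102 given 3' UTR length), which argues against those 2 as the source of the trend, and no biological explanation was tested.

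The IP libraries correlated less with each other (mean 0.853 over genes, log2 CPM) than with the Input (0.874). Thinned to the same depth of 10031072 counts, the Input to IP mean was still higher by 0.0197, which argues against unequal depth. The SD of log2 CPM between IP libraries was 3.19 times larger at 5 to 20 CPM than at 200 CPM or more. At 5 to 20 CPM its median was 0.927, against 0.0988 from counting error alone, so counting error does not account for that spread. Few starting RNA molecules in the IP would widen the spread between single libraries. Differences between animals would too, if the IP libraries came from separate animals, which the labels did not say. These causes cannot be told apart here without further Input libraries to compare.

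Endothelial markers were higher in IP while astrocyte, oligodendrocyte and microglial markers were lower by camera, calls that were lost with an estimated correlation (adjusted p = 0.197 for endothelial and microglial markers, 0.406 for astrocytes and 0.320 for oligodendrocytes). The most abundant endothelial genes, Slc2a1 and Flt1, reached 153 ± 136 and 51.9 ± 39.9 CPM in IP. A lower share of every other cell type would move all of them alike, but the endothelial median exceeded that of these 3 glial lists together by at least 3.12 (log2) in each IP library. The endothelial median lay at the 100th percentile of random lists matched on mean expression over all libraries, which argues against low mean counts. Those lists were not matched on the Input, so they cannot decide on low counts in the Input alone. A single IP library does not account for the pattern either, since the lowest library median was 1.71. All 3 ratios share the lone Input, though, so a cause in that library cannot be told apart. No biological explanation was tested, and 0 of the 14 markers were called singly by edgeR (4 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom).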
